A study of Homo sapiens with 6 samples.

How the data were processed

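Gene expression was measured in BE(2)-C cells, a human neuroblastoma cell line with amplification of the MYCN oncogene, after 6 h with vehicle, THZ1 (a covalent inhibitor of the transcriptional kinase CDK7), ponatinib (a multi-target tyrosine kinase inhibitor), lapatinib (an inhibitor of EGFR and HER2), THZ1 with ponatinib, or THZ1 with lapatinib. Per the labels, THZ1 was used at 32 nM, ponatinib at 250 nM and lapatinib at 1000 nM. The doses are not restated for the combinations. Each of the 6 treatments has 1 Affymetrix Human Gene 2.0 ST array, for which 100 ng of total RNA was amplified and labelled, per the labels' protocols.

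The value table deposited by the authors holds log2 expression values of 53617 features, normalised between arrays. The software, the normalisation method and the genome build are not given in the sources used here, so no coordinates are printed. The authors' deposited table of signed fold values against vehicle was used only as a check: for all 53617 features its fold equals the difference of the 2 arrays in the log2 table to within 9.91e-09, which settles the log base and the direction. Equal amounts of RNA were labelled and the arrays share nearly the same distribution, so a fall in the total RNA of the cells cannot be seen in these values. The medians and interquartile ranges of the deposited arrays are given with the results.

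Gene symbols came from the deposited table, where 29548 features carry 1 symbol, 2506 carry several and 21563 carry none. Symbols were updated through the RefSeq annotation of GRCh38.p14, used for names only: 26253 features carried a current symbol, 1214 were updated through a synonym and 2081 were kept as given. No gene was named from a feature with several symbols, which leaves out ERBB2, the gene of HER2. Of the 26665 named genes, 1489 have several features, and the brightest over the 6 arrays was used. A gene was counted as above the level minimum at 4.82 log2 units, the median of all named genes. For the tests, 13333 genes with a mean at or above this level were kept.

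With 1 array per treatment, a difference between 2 arrays has no replicate check and no p-value. Genes were counted by size, when they differed at least 2-fold and the brighter array was at or above the level minimum. Genes named by this rule are marked dim where another array of the comparison was under it. The deposited table has no detection values, so the level minimum is not a measured background. The genes named are, for each difference from vehicle, up to 10 in each direction with the largest difference past that rule, and up to 5 in each direction for differences from THZ1 alone and for interaction values. Small RNA genes and unnamed loci were counted but not named. From each of 22 gene lists, up to 4 members with the largest difference were eligible to be named, and the levels of MYCN, HAND2, GATA3, CDK7, EGFR, FGFR1, PDGFRA, RET, KIT and ALK were always reported. These rules and the lists were fixed before the data were examined. Genes named outside them are said to be so. Some genes that meet these rules are not reported here.

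The lists covered adrenergic and mesenchymal neuroblastoma transcription factors, immediate-early genes, ERK pathway output and feedback genes, E2F and DNA replication genes, mitotic genes, DNA damage response and repair genes, p53 target genes, integrated stress response genes, ER chaperone genes, cholesterol synthesis genes, heat shock genes, RNA polymerase II kinase and elongation genes, receptor and Src-family kinase genes, FOXO target genes, BCL2 family and apoptosis inhibitor genes, catecholamine and neuronal genes, MYC and ribosome biogenesis target genes, ribosomal protein genes, interferon and NF-kB response genes, Schwann cell and fibroblast marker genes, and KRAB zinc finger genes. Of their 557 entries, 528 had a feature with 1 symbol and 441 were above the level minimum. A list's median log2 difference was placed among 10000 random lists of the same size matched on mean level in 20 bins. This percentile describes the arrays compared and is not a p-value, because genes of a list vary together. In a test of the percentile on lists of 20 unrelated genes, 4 of 100 lists fell below the central 95% of random lists and 2 above it. With every gene of the list shifted by -0.2, all 100 fell below it.

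The 6 arrays form a layout of THZ1 (without, with) and partner (none, ponatinib, lapatinib). Tests were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjustment over 13333 genes) in an additive model of THZ1 and partner, which leaves 2 residual degrees of freedom. It takes the same drug step in different partner settings as repeats, so its residual holds array error together with any interaction between drugs. Nothing in the labels says that the arrays came from separate cultures, so the spread may be technical. Gene lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the 22 lists. With an estimated correlation camera takes the 2 residual degrees of freedom, so only a very large statistic could pass. A call lost there does not by itself show that correlation between genes produced it. A model that takes ponatinib and lapatinib as repeats of an inhibitor arm and adds an interaction term was chosen after seeing the data, as were the list tests for the inhibitor terms.

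The fit was tested on simulated data of 13333 genes of which 200 were changed. The THZ1 term recovered 77.6% of genes changed by 0.5 log2 units and 100% of those changed by 1 or 2, with 17 false among 202 calls. In a separate simulation the interaction term recovered 4.5%, 67.2% and 100% at these sizes, with 9 false among 123 calls. The simulated noise was normal and independent between arrays, and the THZ1 simulation held no interaction between drugs. The real residual can hold both shared error and interaction, so these shares do not give the power of the fit on the real arrays. Alternatives were no filter on dim genes, quantile normalisation of the deposited values, the mean of all features of a gene, a 1.5-fold threshold, an intensity trend in the variance prior, leaving out pairs of arrays, and a model without the partner term. Summaries and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.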

Results

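Messenger RNA levels were compared across 6 arrays of MYCN-amplified BE(2)-C neuroblastoma cells treated for 6 h, with 1 array each for vehicle, THZ1, ponatinib, lapatinib, THZ1 with ponatinib and THZ1 with lapatinib. The array medians lay between 4.23 and 4.26 log2 units. The interquartile range was 3.19 on the vehicle array, 3.17 with THZ1, 3.15 with ponatinib, 3.17 with lapatinib, 3.10 with THZ1 and ponatinib and 3.05 with THZ1 and lapatinib. No treatment was replicated, so differences between 2 arrays are given by size, with no error, and the number of arrays limits their precision. MYCN itself was bright, at 12.28 log2 units with vehicle, and differed from vehicle by -0.05 with THZ1, -0.10 with ponatinib, 0.06 with lapatinib, -0.05 with THZ1 and ponatinib and -0.09 with THZ1 and lapatinib.

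The question for THZ1 alone was what this inhibitor of CDK7, a kinase of the general transcription machinery, did to transcript levels at 32 nM. The arrays do not measure which kinases it inhibited. Few genes moved far: 3 genes were at least 2-fold higher and 12 at least 2-fold lower than with vehicle, and all 3 of the former and 7 of the latter were small RNA genes. The nameable genes were DNM1P46 (a pseudogene, -1.28), MAPT-IT1 (dim, -1.23), FAM238C (dim, -1.22) and TRIM74 (dim, -1.04), all log2 differences. Here and below, a gene marked dim had an array of the comparison under the level minimum of 4.82 log2 units, so the size of its difference and its order among the genes are not read. Genes named as members of a list are not marked, though some had an array under it, such as FBXO32 (4.512 with vehicle) and TP53INP1 (4.345 with vehicle). DNM1P46 was also lower than vehicle with every other treatment, by -0.71 to -1.15, so the vehicle array alone stood high for it. The difference for MAPT-IT1 was -0.52 with the mean of its features, and that for TRIM74 was -0.99 after quantile normalisation. CDK7 was at 7.52 log2 units with vehicle and differed by 0.16 with THZ1, 0.16 with ponatinib, 0.20 with lapatinib, 0.19 with THZ1 and ponatinib and 0.40 with THZ1 and lapatinib.

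FOXO target genes, which include cell cycle brakes and regulators of protein turnover, lay higher with THZ1 alone. The list's median difference was 0.14, at percentile 99.64 of random lists, with 15 of 17 members positive, among them FBXO32 (a muscle-atrophy ubiquitin ligase, 0.57), KLF9 (0.41), CCNG2 (cyclin G2, 0.41) and BCL6 (0.33). DNA damage response and repair genes lay lower, with a median of -0.07 at percentile 0.06 and 16 of 24 members negative. Ribosomal protein genes had a median of -0.03 at percentile 1.26, with RPLP2 at -0.51 and RPL32 at -0.40. Among RNA polymerase II kinase and elongation genes, HEXIM1, an inhibitor of the elongation factor P-TEFb, was 0.47 higher and POLR2A, the largest subunit of the polymerase, 0.31 higher (list percentile 94.80). If the genes of a list varied independently, 1.1 of the 22 lists would lie outside the central 95% of random lists, and 3 did with THZ1.

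Ponatinib was compared with vehicle to show what a multi-target tyrosine kinase inhibitor did alone at 250 nM. JUN, an AP-1 transcription factor gene, was 3.57-fold lower (-1.84), the largest difference of a nameable gene that was not dim with any single drug. The other nameable genes among 6 that were at least 2-fold lower were RPS6KL1 (-1.13) and UTS2R (-1.03). Of 4 that were higher, TP53INP1, a p53-inducible gene, differed by 1.19 (dim) and MAP2K6, a kinase that activates p38, by 1.09. The remaining 3 lower and 2 higher genes were small RNA genes.

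Genes that ERK signalling switches on, including its own feedback inhibitors, lay lower with ponatinib. Of 14 ERK pathway output and feedback genes 12 were negative, with a median of -0.29 at percentile 0.00, led by the phosphatase gene DUSP4 (-0.85), the Sprouty gene SPRY4 (-0.71) and the ETS factor gene ETV5 (-0.71). Immediate-early genes had a median of -0.14 at percentile 0.05, with IER2 at -0.50, ATF3 at -0.49 and JUNB at -0.41 besides JUN. Mitotic genes lay higher, with a median of 0.12 at percentile 100.00 and 21 of 24 members positive, including CDC25C (0.62), CENPE (0.29) and KIF20A (0.28). Cholesterol synthesis genes had a median of 0.11 (percentile 99.99), FOXO targets 0.16 (99.94; CCNG2 0.89, FBXO32 0.70), DNA damage response and repair genes 0.09 (99.86), adrenergic transcription factors 0.07 (99.62) and integrated stress response genes 0.09 (99.48). In all, 8 of 22 lists lay outside the central 95% of random lists.

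Lapatinib, which targets EGFR and HER2, was the treatment with the fewest differences from vehicle, at 1000 nM. No gene was at least 2-fold higher and 6 were lower, 3 of them small RNA genes and the rest LTB4R2 (a leukotriene receptor gene, dim, -1.15), DNM1P46 (-1.14) and ANKRD36BP1 (-1.09). EGFR was at 9.56 log2 units with vehicle and differed by 0.10. All 23 cholesterol synthesis genes above the level minimum were positive, with a median of 0.08 at percentile 99.81 and INSIG1 at 0.28. The p53 targets (median 0.12, percentile 99.86) and FOXO targets (0.11, 99.60) also lay higher. Immediate-early genes (-0.08, 0.83; FOS -0.70) and KRAB zinc finger genes (-0.08, 0.70) lay lower. The ERK output list was at -0.03, percentile 20.10.

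**Figure D1:**
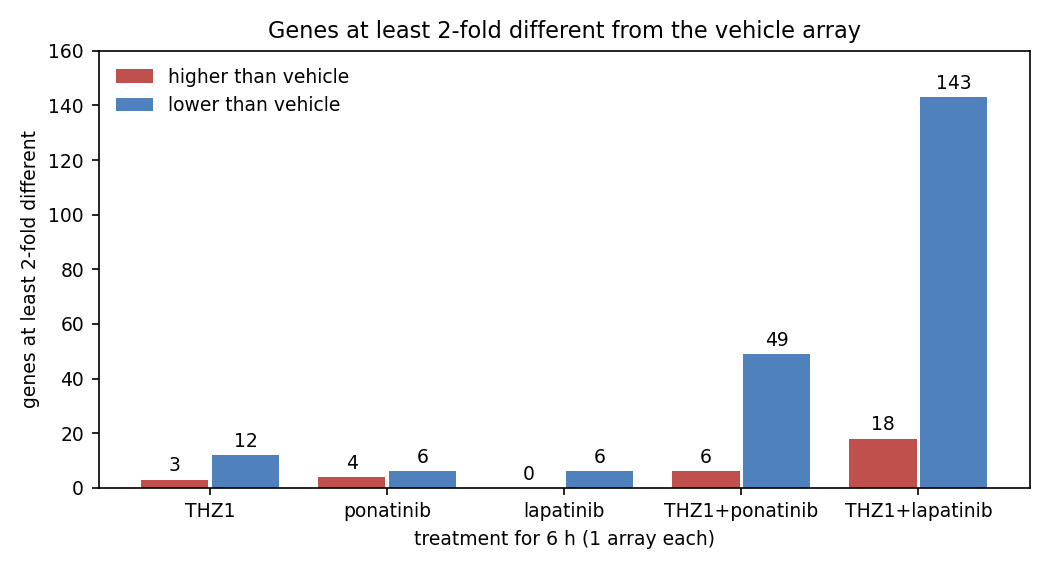
Number of genes at least 2-fold higher (red) or lower (blue) than on the vehicle array for each treatment, 1 array each, with the treatment on the horizontal axis and the gene count on the vertical axis. The number of lower genes is 12 or fewer for each single drug, 49 with THZ1 and ponatinib and 143 with THZ1 and lapatinib.

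THZ1 with ponatinib was compared with vehicle to show what the combination did. A larger set of genes was lower than with any single drug: 49 genes were at least 2-fold lower and 6 higher. KRCC1 was 4.87-fold lower (-2.29) and PPP1R10, which encodes the nuclear targeting subunit PNUTS of protein phosphatase 1, was 4.51-fold lower (-2.17). JUN was 4.22-fold lower (-2.08). The other genes named were the zinc finger gene ZNF429 (dim, -1.57), the centrosomal gene CEP19 (-1.56), the axonemal gene RIBC2 (dim, -1.49), the tRNA-modifying enzyme gene LCMT2 (-1.40), the serotonin receptor gene HTR2B (-1.37), ZC3H4, whose product restrains non-coding transcription (-1.35), and MOCS3 (-1.32). The nameable genes at least 2-fold higher were RPS6KA5, which encodes the kinase MSK1 (1.26), CCNG2 (1.06) and FBXO32 (dim, 1.04).

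In this combination the ERK output list lay close to where it was with ponatinib alone, with a median of -0.28 at percentile 0.02 and DUSP4 at -0.83, ETV5 at -0.71 and SPRY4 at -0.68. E2F and DNA replication genes had a median of -0.10 (percentile 0.13), with 19 of 27 negative, among them GINS1 (-0.60) and CDCA7 (-0.57). DNA damage response and repair genes had a median of -0.08 (percentile 2.46; XRCC2 -0.53, BRCA2 -0.46) and KRAB zinc finger genes -0.13 (percentile 1.39). FOXO targets were at 0.22 (percentile 99.98), mitotic genes at 0.09 (99.72), cholesterol synthesis genes at 0.09 (99.15), and RNA polymerase II kinase and elongation genes at 0.07 (97.76), where POLR2A was 0.93 and CCNT2 0.44 higher. BCL2, an inhibitor of apoptosis, differed by -0.68, while the median of the BCL2 family and apoptosis inhibitor list was -0.09 (percentile 9.25).

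THZ1 with lapatinib differed most from vehicle, with 143 genes at least 2-fold lower and 18 higher. After quantile normalisation the counts were 116 and 28. PPP1R10 was 6.57-fold lower (-2.72), and KRCC1 (dim, -2.87) and ZNF429 (dim, -2.62) were also lower. ZNF429 was at 3.14 log2 units on this array. The other genes named were the delta-tubulin gene TUBD1 (-1.92), the zinc finger genes ZFP3 (-1.91) and ZNF691 (dim, -1.85), ZC3H4 (-1.68), MOCS3 (-1.59), and the pseudogenes PDIA3P1 (dim, -1.57) and PRKXP1 (-1.57, or -0.76 with the mean of its features). The higher genes included HEXIM1 (1.13), ID4, an inhibitor of DNA binding by helix-loop-helix factors (dim, 1.14), the ceramidase gene ACER2 (dim, 1.05), the stress-response gene GADD45B (1.03), ZNF615 (1.04), ALMS1-IT1 (dim, 1.29), POTEC (dim, 1.105) and RIMBP3B (dim, 1.03). Small RNA genes and unnamed loci made up 22 and 21 of the lower genes and 6 and 4 of the higher genes.

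Adrenergic neuroblastoma transcription factors, which hold the identity circuit of these cells, lay lower with THZ1 and lapatinib. The list's median was -0.14 at percentile 0.44, with 17 of 21 members negative, among them ZNF536 (-0.62), HAND2 (-0.61) and TBX2 (-0.52). The same list was at -0.05 (percentile 7.15) with THZ1 and ponatinib. HAND2 was at 10.46 log2 units with vehicle and differed by -0.07 with THZ1, -0.10 with ponatinib, -0.04 with lapatinib and -0.19 with THZ1 and ponatinib. GATA3 was at 10.07 and differed by -0.11, 0.07, -0.11 and -0.05 in that order, and by -0.26 with THZ1 and lapatinib. DNA damage response and repair genes had a median of -0.12 (percentile 1.84), with 20 of 24 negative and XRCC2 (-0.87), PALB2 (-0.74), BRCA2 (-0.70) and RAD51C (-0.51) lowest. FOXO targets were at 0.17 (percentile 99.83; CDKN2B 0.74, KLF9 0.62) and p53 targets at 0.12 (99.23; TP53INP1 0.70, SESN2 0.42). POLR2A was 0.94 higher and BRD2 0.56 higher, with the RNA polymerase II list at percentile 92.98. Among immediate-early genes EGR1 was at -1.03 and NR4A2 at 0.92, and the list lay at percentile 34.70.

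**Figure D2:**
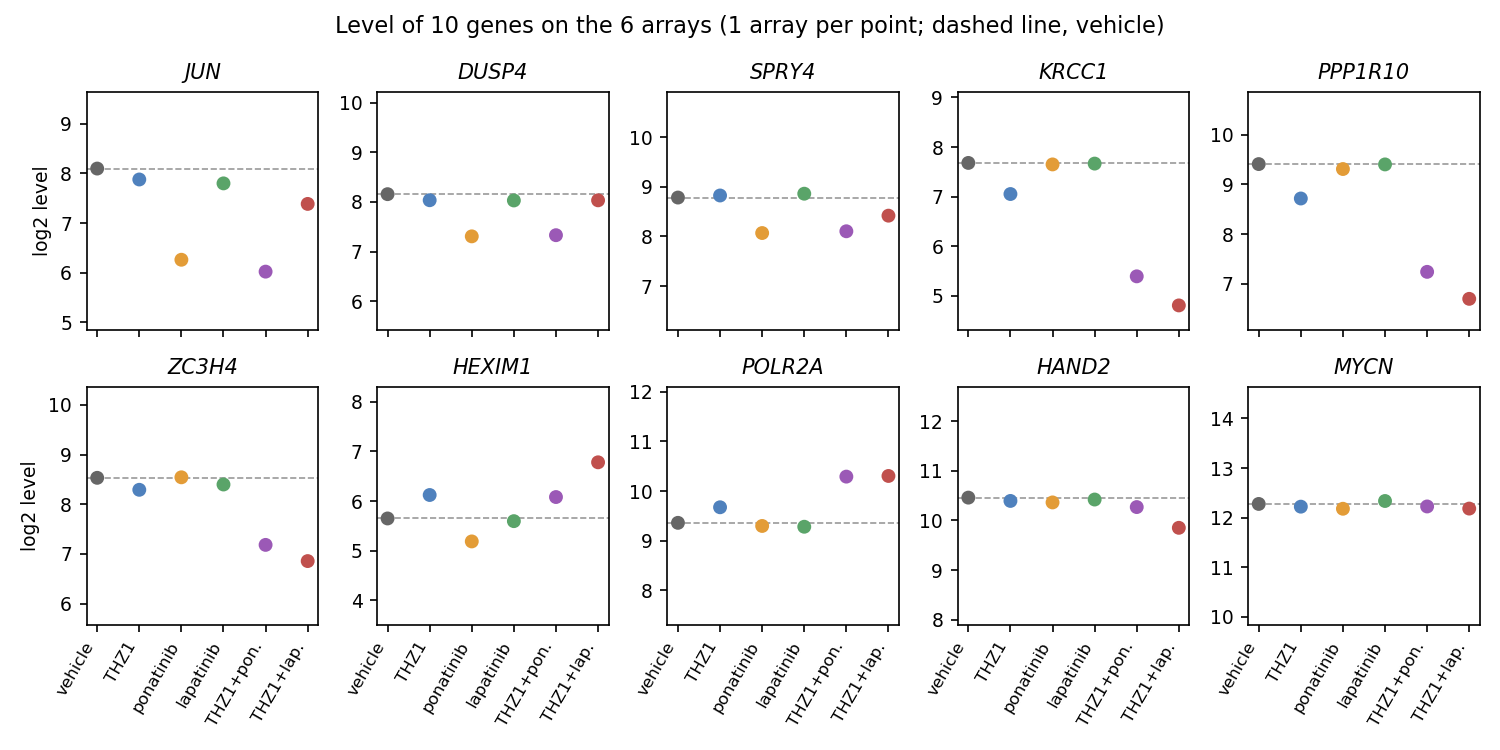
Log2 level of 10 genes on the 6 arrays, 1 point per array, with treatments on the horizontal axis, a dashed line at the vehicle level and axes of equal span. JUN, DUSP4 and SPRY4 lie lower on both arrays with ponatinib (JUN -1.84 and -2.08 from vehicle), KRCC1, PPP1R10 and ZC3H4 lie lowest on the combination arrays, and MYCN stays within 0.10 of vehicle.

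Adding an inhibitor to THZ1 was then compared with THZ1 alone. With ponatinib added, 42 genes were at least 2-fold lower and 14 higher. The lower genes named were JUN (-1.86), KRCC1 (-1.66), PPP1R10 (-1.48), AQP7 (dim, -1.40) and LCMT2 (-1.20), and the higher ones CSH1 (dim, 1.35), TAFA4 (dim, 1.12), MAPT-IT1 (dim, 1.11, or 0.36 with the mean of its features), ZNRF4 (dim, 1.04, or 0.98 after quantile normalisation) and GRAPL (1.04). The ERK output list was at -0.24 (percentile 0.33; CCND1 -0.54), E2F and DNA replication genes at -0.15 (0.02; 25 of 27 negative, CCNE1 -0.92), KRAB zinc finger genes at -0.16 (1.14), mitotic genes at 0.11 (99.97) and cholesterol synthesis genes at 0.07 (98.96). With lapatinib added, 91 genes were at least 2-fold lower and 15 higher. The lower genes named were KRCC1 (dim, -2.24), ZNF429 (dim, -2.19), PPP1R10 (-2.02), ZFP3 (-1.76) and TUBD1 (-1.68), and the higher ones TGFBR3L (1.21, or 0.47 with the mean of its features), ALMS1-IT1 (1.11), PLAG1 (dim, 1.09), POTEC (dim, 1.085) and SUZ12P1 (1.03). Adrenergic transcription factors were at -0.17 (percentile 0.14; 19 of 21 negative, PHOX2A -0.52), the RNA polymerase II list at 0.07 (99.85), p53 targets at 0.08 (99.36) and cholesterol synthesis genes at 0.04 (97.54).

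Of the genes lower with the combinations, KRCC1, PPP1R10, ZNF429 and ZC3H4 were close to vehicle with either inhibitor alone, whereas JUN was already at -1.84 with ponatinib alone. KRCC1 differed from vehicle by -0.63 with THZ1, -0.03 with ponatinib and -0.01 with lapatinib, and PPP1R10 by -0.69, -0.10 and -0.01. ZNF429 differed by -0.44, -0.05 and 0.12, and ZC3H4 by -0.24, 0.01 and -0.13. The interaction value, the difference of the combination from THZ1 minus that of the inhibitor from vehicle, was at least 1 log2 unit in size for 120 genes with ponatinib (49 higher, 71 lower) and 175 with lapatinib (44 higher, 131 lower). With ponatinib the lower ones included KRCC1 (-1.63), UBE2Q2P16 (dim, -1.54), IFT70A (dim, -1.53) and TBX22 (-1.48), and the higher ones MAPT-IT1 (dim, 1.68), STH (1.52), HHIPL1 (dim, 1.43), UTS2R (1.32) and SCX (dim, 1.29). With lapatinib the lower ones included PPP1R10 (-2.01), TUBD1 (-1.79), ZNF429 (dim, -2.30), KRCC1 (dim, -2.23) and PDIA3P1 (dim, -1.92), and the higher ones SUZ12P1 (1.73), DNM1P46 (1.71), STH (1.44), LTB4R2 (dim, 2.01) and GCSH (dim, 1.48). Each value rests on 4 arrays and includes the error of all of them, and both sets share the vehicle and THZ1 arrays. A high vehicle array raises the value and a low one lowers it. DNM1P46, UTS2R and MAPT-IT1 were lower than vehicle with every treatment, and UBE2Q2P16 was higher with every treatment. Their values may therefore reflect the vehicle array alone.

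The THZ1 step was next read on arrays that do not overlap, as THZ1 with ponatinib against ponatinib and THZ1 with lapatinib against lapatinib. KRCC1 (-2.26 and, dim, -2.86), PPP1R10 (-2.07 and -2.71), TUBD1 (-1.21 and -2.03) and ZC3H4 (-1.36 and -1.54) were lower in both steps, while POLR2A (0.99 and 1.02) and HEXIM1 (0.89 and 1.19) were higher in both. Of 13496 genes, 46 were at least 2-fold lower in the ponatinib setting and 127 in the lapatinib setting, and 30 were shared, against 0.433 for independent lists of these sizes. Across genes the steps correlated with a Pearson r of 0.48 and a Spearman rho of 0.38, where genes are not independent replicates. THZ1 against vehicle correlated less with these steps, at r = 0.09 and 0.26. Ponatinib against vehicle and THZ1 with ponatinib against THZ1 correlated at r = 0.14, and the corresponding lapatinib steps at r = 0.03. Pairs with the other inhibitor gave similar values, r = 0.10 for ponatinib against vehicle with lapatinib added to THZ1 and r = 0.04 for lapatinib against vehicle with ponatinib added to THZ1. Across the ponatinib pair 2 genes were at least 2-fold lower in both steps, JUN and the microRNA gene MIR300 (dim). The latter, named here after its values were seen, was also lower when lapatinib was added to THZ1 (-1.46).

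**Figure D3:**
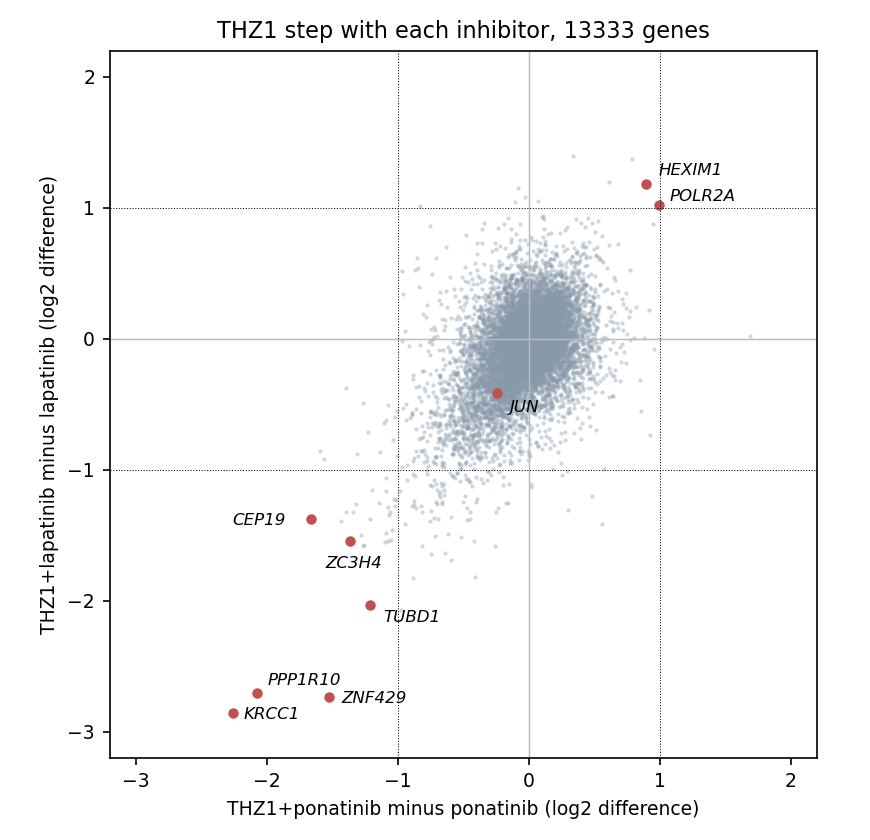
Log2 difference of 13333 genes in the THZ1 step with ponatinib (horizontal axis) and with lapatinib (vertical axis), 1 point per gene, with dotted lines at 2-fold. The steps share no array, and KRCC1, PPP1R10, ZNF429, TUBD1, CEP19 and ZC3H4 lie beyond 2-fold lower in both, with POLR2A at 0.99 and 1.02.

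In the additive limma model of all 6 arrays, no gene passed an adjusted p of 0.05 for THZ1, ponatinib, lapatinib or ponatinib against lapatinib. At an unadjusted level of 0.05, 1724, 979, 680 and 626 of 13333 genes passed. Here and below, a share of 0.05 of the genes would pass this level if none had changed. The counts for lapatinib and for ponatinib against lapatinib lie near that share. JUN came nearest: it was lower in both ponatinib steps, with a fitted difference of -1.85 ± 0.09 (SE) and an adjusted p of 0.0538. That adjusted p was 0.0251 after quantile normalisation, 0.00284 with an intensity trend and 0.0149 without both lapatinib arrays, and up to 0.212 over the alternatives. JUN differed between ponatinib and lapatinib by -1.45 ± 0.09, with an adjusted p of 0.184, or 0.0155 with an intensity trend and up to 0.755 over the alternatives. For THZ1, KRCC1 had a fitted difference of -1.91 ± 0.42, PPP1R10 of -1.82 ± 0.37 and HEXIM1 of 0.85 ± 0.14, each with an adjusted p of 0.351.

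When ponatinib and lapatinib were taken as repeats of an inhibitor arm, a model chosen after seeing the data, limma found 20 genes changed by THZ1 in the presence of an inhibitor, 1 higher and 19 lower. POLR2A rose (1.01 ± 0.08 SE, adjusted p = 0.0417). KRCC1 (-2.56 ± 0.19) and PPP1R10 (-2.39 ± 0.18) fell, both with an adjusted p of 0.0417. CEP19 (-1.52), ZC3H4 (-1.45), the Fanconi anaemia gene FANCF (-1.42) and CSTF3, a cleavage stimulation factor of polyadenylation (-1.18), also fell, with adjusted p-values of 0.0417 to 0.0475. FANCF and CSTF3 lie outside the naming rules and were named after their values were seen. The additive model fitted to the same 4 arrays with an inhibitor called 0 genes for THZ1, with 2145 at an unadjusted level of 0.05. The interaction term passed for 0 genes, with 929 at an unadjusted level of 0.05.

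The gene lists were tested in the additive model with camera. For THZ1, DNA damage response and repair genes fell (median -0.15, 20 of 24 negative) and FOXO targets rose (median 0.13, 15 of 17 positive), each with an adjusted p of 0.00191. With an estimated correlation, and so 2 residual degrees of freedom, the adjusted p was 0.96 for both. The estimated correlation was 0.3754 for the repair list. For the FOXO list it was -0.0128, below the preset 0.01, so correlation did not remove that call. In the 3 THZ1 steps that share no array, the repair list lay at percentiles 0.06, 0.20 and 0.13 and the FOXO list at 99.64, 97.71 and 98.68. Adjusted over the list alone, 3 of 23 RNA polymerase II kinase and elongation genes and 3 of 22 immediate-early genes rose with THZ1, against 0 of each over all genes tested. The adjusted p of these lists was 0.0617 and 0.447.

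For ponatinib, 7 lists passed camera with the preset correlation, and with an estimated correlation each of these calls was lost. The latter test has 2 residual degrees of freedom. Calls were lost even where the estimated correlation was below the preset 0.01, for mitotic genes (0.0049), FOXO targets (-0.0128) and MYC targets (-0.0264). ERK output genes fell, with all 14 fitted differences negative, a median of -0.23 and an adjusted p of 5.3e-07 (0.543 with an estimated correlation). Adjusted over the list alone 6 of them fell, against 0 over all genes tested. E2F and DNA replication genes fell (median -0.11, 25 of 27 negative, adjusted p = 3.18e-04) and mitotic genes rose (median 0.09, 19 of 24 positive, adjusted p = 3.18e-04), both with 0.543 with an estimated correlation. Cholesterol synthesis genes (median 0.10, 19 of 23 positive) and FOXO targets (median 0.11, 13 of 17 positive) rose, each with an adjusted p of 0.00805, or 0.597 and 0.543 with an estimated correlation. Immediate-early genes (median -0.05, 17 of 22 negative, adjusted p = 0.0304) and MYC and ribosome biogenesis targets (median -0.07, 20 of 24 negative, adjusted p = 0.0306) fell, both with 0.543 with an estimated correlation. The immediate-early list lay at percentile 0.05 with ponatinib against vehicle but at 53.06 with ponatinib added to THZ1, and the MYC list at 4.02 and 9.73. Adjusted over the list alone, 1 FOXO target rose and 1 immediate-early gene fell. For lapatinib no list passed, and p53 targets, cholesterol synthesis genes and FOXO targets had an adjusted p of 0.0552.

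Ponatinib and lapatinib, at their different doses, were compared directly in the same model. ERK output genes were lower with ponatinib than with lapatinib by a median of -0.23 (12 of 14 negative, adjusted p = 5.3e-07), and mitotic genes higher by 0.13 (23 of 24 positive, adjusted p = 1.72e-06). With an estimated correlation, and so 2 residual degrees of freedom, both had an adjusted p of 0.555. Between the arrays without THZ1, 9 genes were at least 2-fold higher and 2 lower with ponatinib than with lapatinib. Between the combinations, 19 were higher and 14 lower with ponatinib. The adrenergic list differed in sign between these settings: its median was -0.06 (12 of 21 negative, percentile 2.67) without THZ1 and 0.21 (21 of 21 positive, percentile 100.00) with it.

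**Figure D4:**
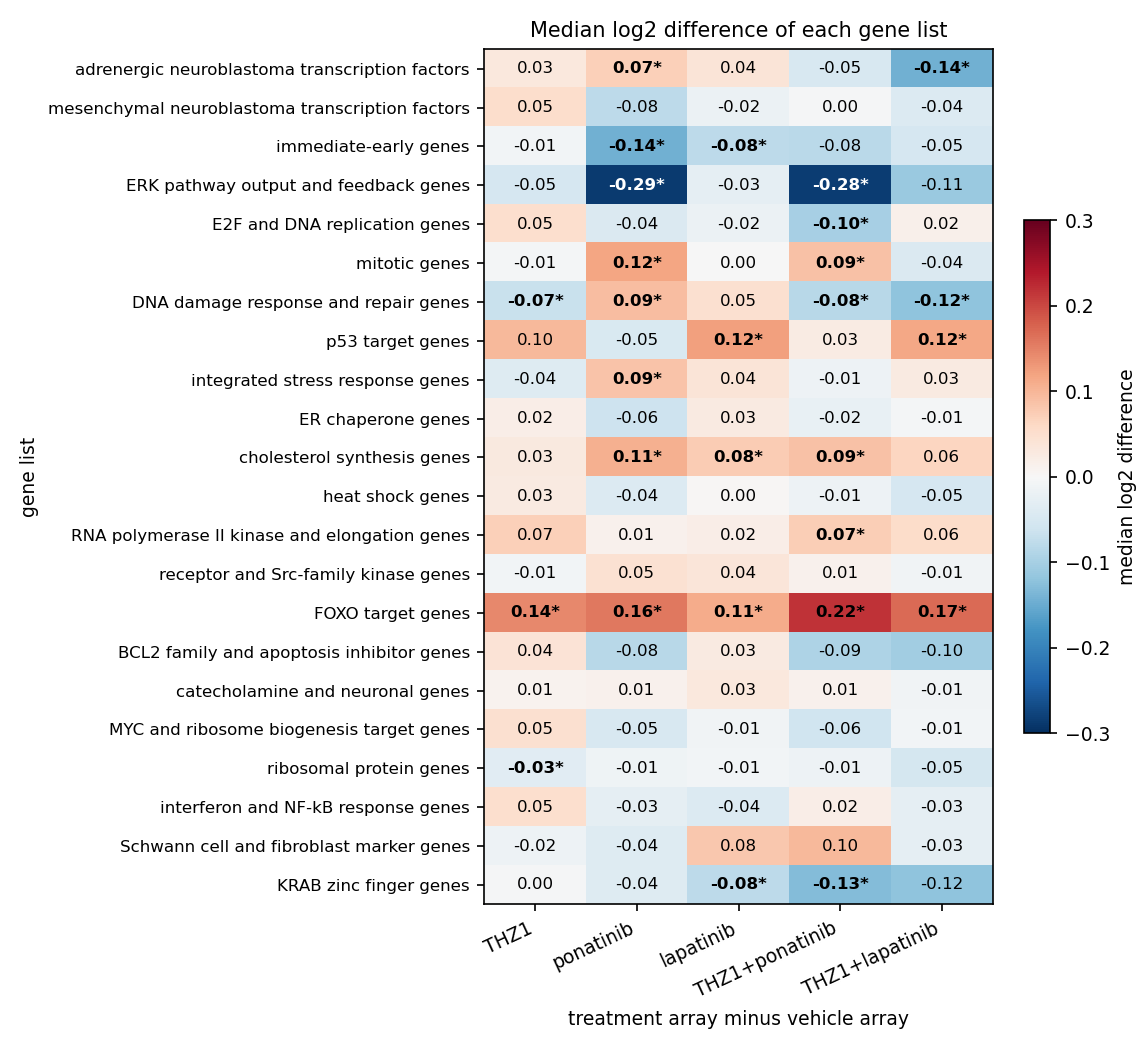
Median log2 difference from vehicle of 22 gene lists (vertical axis) with each treatment (horizontal axis), over members above the level minimum. Bold values with an asterisk lie outside the central 95% of random lists, and FOXO targets do so with all 5 treatments (0.11 to 0.22), which share the vehicle array.

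The remaining lists stayed inside the central 95% of random lists over the 5 differences from vehicle. Medians ranged from -0.08 to 0.05 for mesenchymal transcription factors, from -0.06 to 0.03 for ER chaperone genes, from -0.05 to 0.03 for heat shock genes, from -0.01 to 0.05 for receptor and Src-family kinase genes and from -0.01 to 0.03 for catecholamine and neuronal genes. They ranged from -0.06 to 0.05 for MYC and ribosome biogenesis targets and from -0.04 to 0.05 for interferon and NF-kB response genes, of which 9 were above the level minimum. Markers of Schwann cells and fibroblasts, fixed as a check for other cell types, had 7 genes above it and medians from -0.04 to 0.10. Among receptor kinase genes, RET was at 8.88 log2 units with vehicle and differed by -0.24, -0.09, -0.08, -0.30 and -0.31 with THZ1, ponatinib, lapatinib, THZ1 with ponatinib and THZ1 with lapatinib. In the same order EGFR differed by -0.09, 0.07, 0.10, -0.18 and -0.34, FGFR1 (5.31 with vehicle) by 0.29, -0.21, 0.07, -0.05 and -0.01, and ALK (5.95 with vehicle) by -0.09, 0.20, 0.15, 0.19 and 0.06. PDGFRA (3.64) and KIT (3.81) were below the level minimum. No list median outside the central 95% of random lists changed sign with quantile normalisation or the mean of features. Of all 242 list medians, 42 changed sign with quantile normalisation and 4 with the mean of features.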

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

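The overlap of the THZ1 steps, the dim-gene correlation, the interaction fit, both tests of the ERK genes and the direct list tests between inhibitors were chosen after the results were seen. The test of array spread and the count of splits were set before.

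Many more genes lay at least 2-fold lower on the combination arrays than with any single drug. A narrower spread of values on these arrays is argued against, since 116 genes stayed lower with THZ1 and lapatinib after quantile normalisation, against 12 with THZ1 alone. Independent noise of each combination array is argued against by the 30 genes shared between THZ1 steps without a common array, 69.3 times the number for independent lists. Independent lists are a low bar, because steps of different inhibitors without a common array also shared more genes than such lists. At 1.5-fold lower the ratio was 12.0 for the THZ1 steps. It was 5.2 for ponatinib against vehicle with lapatinib added to THZ1, and 4.9 for lapatinib against vehicle with ponatinib added to THZ1. At 1.5-fold higher the ratios were 7.8, 21.2 and 9.5 in that order, so the THZ1 steps did not exceed the other pairs there. At 2-fold lower the pairs of different inhibitors shared 1 gene (ratio 30.7) and 0 genes in the same order. A preparation batch shared by both combination arrays and a response to THZ1 that is larger with an inhibitor cannot be told apart here. No batch is named, and the steps correlated at 0.0169 over dim genes, which carry little signal. The interaction passed for 0 genes (KRCC1 -1.93 ± 0.33 SE, adjusted p 0.63). The same fit recovered 67.2% of simulated genes at 1 log2 unit and 100% at 2, with noise drawn independently for each array. Those shares do not give its power on the real arrays, so the absence of calls decides nothing. For THZ1 across partners all 10 splits of the 6 arrays called as many genes as the real grouping, which called 0 with 0 as the highest of the others, and 10 splits are too few for a share under 0.05.

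ERK output genes lay lower with ponatinib. A shift of all genes of their level is argued against, since the list lay at percentile 0.33 or lower in both ponatinib steps, which share no array. Whether lapatinib shared part of this effect stays open. The list lay at percentiles 20.10 and 17.00 in the lapatinib steps. Camera gave an adjusted p of 5.3e-07 for ponatinib against lapatinib, but 0.555 with an estimated correlation. With 2 residual degrees of freedom the latter test could hardly pass, so 0.555 decides nothing. The requirement that the difference also pass with an estimated correlation was added after that value was known. Different targets of the drugs are a candidate explanation that these arrays did not test, and the doses differed.

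In the direct comparison of ponatinib with lapatinib, 7 lists differed by camera with the preset correlation. None did with an estimated one, which leaves the test 2 residual degrees of freedom. The median differences were -0.2267 for ERK output genes, 0.1312 for mitotic genes, -0.0791 for E2F and DNA replication genes, -0.106 for immediate-early genes, 0.0583 for DNA damage response and repair genes, -0.082 for MYC and ribosome biogenesis targets and 0.0739 for adrenergic transcription factors. This last value averages opposite signs, -0.06 without THZ1 (percentile 2.67) and 0.21 with it (percentile 100.00). Features left out of the gene analysis also passed 2-fold, in both directions. Of 21563 features without a symbol, 238 were at least 2-fold lower than vehicle with THZ1 and ponatinib and 233 with THZ1 and lapatinib, against 163 with THZ1, 132 with ponatinib and 139 with lapatinib. In that order, 128 and 227 were at least 2-fold higher with the combinations, against 133, 110 and 120. Of 2506 features with several symbols, 6 were lower with THZ1 and ponatinib and 6 with THZ1 and lapatinib, against 2 to 3 with single drugs, and 3 and 2 were higher, against 1 with each single drug.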

How the results depend on the processing

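The interaction model and the list tests for the inhibitors were chosen after seeing the data; all other alternatives here were set before. With 1 array per treatment no count carries an error between replicates, and signal over background limits what can be read for dim genes. Without the filter on dim genes the number of genes at least 2-fold different was 61 for THZ1, 43 for ponatinib, 39 for lapatinib and 87 for THZ1 with ponatinib against vehicle, and 131 and 170 for ponatinib and lapatinib added to THZ1, because more genes enter the count. At a 1.5-fold threshold the same 6 counts were 200, 151, 105, 540, 535 and 699, and THZ1 with lapatinib against vehicle gave 883. Quantile normalisation and the mean of features kept all 7 counts within 1.5 times. In limma, ponatinib across THZ1 called 1 gene, JUN, after quantile normalisation, with an intensity trend, and without both lapatinib arrays (1 gene in that single leave-out), and ponatinib against lapatinib called 1 gene with an intensity trend; the cause was not tested. THZ1 and lapatinib called 0 genes under each alternative run. The 2 gene lists called for THZ1 became 0 with an estimated correlation and 0 with fry. The estimated correlation brings the test down to 2 residual degrees of freedom. The FOXO list lost its call though its estimated correlation, -0.0128, was below the preset 0.01. The cause for fry was not tested. Of the named genes' differences, 61 stayed past the size rule after quantile normalisation and 2 did not, and with the mean of features 59 did and 4 did not. No called result reversed.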

Other observations

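The histone and zinc finger tests in this part were chosen after the results were seen.

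Replication-dependent and linker histone genes, 50 of which were above the level minimum, lay lower in each step that added ponatinib or lapatinib. Their median difference was -0.11 with ponatinib against vehicle (35 of 50 negative, percentile 0.00 of random lists), -0.12 with lapatinib against vehicle (36 negative, percentile 0.00), -0.15 with ponatinib added to THZ1 (38 negative, percentile 0.00) and -0.13 with lapatinib added to THZ1 (40 negative, percentile 0.12). The sign held in these 4 steps after quantile normalisation, with medians of -0.07, -0.10, -0.10 and -0.09, and with the mean of features. In the steps that added THZ1 the medians were 0.08 (34 of 50 positive, percentile 99.87) against vehicle, -0.01 (percentile 32.07) against ponatinib and 0.03 (percentile 96.27) against lapatinib, or 0.07, 0.02 and 0.07 after quantile normalisation. The combinations differed from vehicle by a median of -0.08 (percentile 0.29) with ponatinib and -0.07 (percentile 5.05) with lapatinib. After quantile normalisation these were -0.05 and 0.0048, so the sign for THZ1 with lapatinib depended on the scaling. The inhibitor steps against vehicle share that array, and those against THZ1 share the THZ1 array. Histone genes are near-identical copies, so their features are not independent.

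Of 170 genes at least 1.5-fold lower in both THZ1 steps with an inhibitor, 16 (9.41%) carried a zinc finger family symbol, against 418 of 13333 tested genes (3.14%), an odds ratio of 3.298. The idea came from the lowest of these same genes, so the ratio decides nothing about zinc finger genes. The list of KRAB zinc finger genes fixed before the data were examined did not lie outside the central 95% of random lists in these steps, at percentiles 3.85 and 36.80.

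Some lists lay outside the central 95% of random lists on the same side in every step of a drug that shares no array with the others. They were the repair and FOXO lists for THZ1, the ERK, mitotic and cholesterol lists for ponatinib, and the p53 and cholesterol lists for lapatinib. Independent steps would give 0.0007, 0.0275 and 0.0275 of 22 lists if the genes of a list also varied independently. Genes of a list vary together, and the ponatinib and lapatinib steps share the vehicle and THZ1 arrays. These numbers are therefore not a chance rate for the lists found. With quantile normalisation or the mean of features the FOXO list stayed outside in 5 of 6 values and the lapatinib cholesterol list in 3 of 4, and the other 5 lists in every value. This count was also made after the results were seen.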
